A study of Mus musculus with 2 samples.

How the data were processed

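Single-cell RNA-seq was performed on parathyroid glands grown from mouse embryonic stem cells. The hosts lacked Gcm2, a transcription factor needed to form the gland, and had been complemented with stem cells that carry a Pth-tdTomato reporter. In complementation, stem cells placed in the embryo fill the place of an organ that the host cannot form. Replicate 1 pooled glands of 3 mice aged 9 to 12 weeks with 50 to 70% chimerism of blood cells. Replicate 2 pooled glands of 5 mice aged 6 to 13 weeks with 60 to 70%. Both pools held males and females. Per the labels' protocols, glands were digested with papain, collagenase and trypsin, doublets were excluded by flow cytometry, and droplet libraries were made with a 3' kit.

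The deposited values are raw UMI counts per gene and cell barcode. The authors made them with Cell Ranger 7.0.0 on the mouse build mm10, per the submitters' processing notes and the file headers. How barcodes were called as cells is not given in the sources used here. The gene list held 32287 entries, among them tdTomato and Gfp, and the labels do not say what Gfp marks. The files held 1406 barcodes with 41517620 UMIs in replicate 1 and 3518 with 88283761 in replicate 2, at medians of 24345 and 26611.5 UMIs per barcode.

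Barcodes with fewer than 500 genes, at least 15% mitochondrial UMIs or at least 5% haemoglobin UMIs were left out. The haemoglobin limit was added after red cells had been seen within a parathyroid-like cluster. Scrublet predicted 23 doublets (1.64%) in replicate 1 and 6 (0.171%) in replicate 2, at score limits of 0.188 and 0.477, which were removed. In all 1240 and 3313 cells were kept, and 166 and 205 barcodes were left out. An alternative also removed cells with a doublet score of at least 0.25, which 19 and 80 barcodes had.

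Cells of both libraries were clustered together with scanpy 1.11.5, scikit-learn 1.9.0 and python-igraph 0.11.9, on 2000 variable genes, 30 principal components and 15 neighbours, at a Leiden resolution of 1. Cells outside the parathyroid-like clusters were then clustered again in the same way. The 441 list and reporter entries were kept out of the clustering genes. Clusters were named from 154 markers of 23 cell types, by the highest mean log2 ratio, with a score of at least 0.5 and at least 3 detected markers. The markers, gene lists, tests, the rule for named genes and most alternatives were fixed before the data were examined, and the scoring rule and its limits were set afterwards. The ending "like" marks a name that rests on these markers.

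UMI counts were summed per library and class for the 6 classes with at least 20 cells in each library, giving 12 sums. edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test) compared the parathyroid-like class with the unweighted mean of the 5 other classes on the log scale. Library was a block, because the classes of a library come from the same mice, and 5 residual degrees of freedom remained. The replicates were separate pools of mice, and the p-values measure how far class differences vary between these 2 pools. They do not measure how the other classes differ from each other. Calls were made at an adjusted p of 0.05 (Benjamini-Hochberg). Genes used for clustering or naming stayed in the fit and were not counted, which left 11326 of 13385 tested genes eligible.

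CPM values are UMI counts scaled to the total of the class or cluster in its library, computed here. Mean CPM values are given as mean ± SD over the 2 libraries, with the other side the mean over the 5 other classes. The log2 fold change is a mean of logs and can differ from these. Of the genes called higher, 308 had a lower mean CPM than the other classes, and 0 genes called lower had a higher one. The contrast is poorly defined for a gene with no UMI in 1 of the other classes. Of 2865 such genes, 1823 were not called. The count filter keeps a gene with enough counts in 1 class, so that some genes entered only through their highest class.

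The 14 gene lists held 439 genes found in the files; Ero1a and Ero1b were not matched, and Cyr61 was read as Ccn1. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists. Named genes were the 12 largest positive and 12 largest negative log2 fold changes among eligible called genes with the same sign in each library and at least 20 CPM where higher, without mitochondrial, ribosomal protein, Gm-number or Rik genes. Gcm2, Casr and some naming markers were also given. Each list added up to 4 called members of smallest p and the uncalled member of highest CPM. Between replicates the 5 largest ratios each way among genes with at least 50 CPM were named. Genes named within parathyroid-like clusters were chosen among the smallest p after their values were seen. Cilium list members, reporter entries, Mki67, Top2a, Kif23, Pcsk1, Pcsk2, Pcsk5 and the genes named in cells left without a class were also added then.

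In counts simulated over 12088 genes, each gene had 1 mean for all classes, at the sizes of the class and library sums. The genes then changed in the parathyroid-like class were not drawn from the least abundant ones. Of these, 82% of genes changed by 1 and 99% of genes changed by 2 on the log2 scale were recovered, with 21 false calls. The real classes also differ from each other, so that these values do not cover genes absent from 1 of the other classes. Shares of cells have exact binomial and sums of UMIs exact Poisson 95% intervals, which cover counting error only. Where no UMI was found, the limit is that of 3 counts. For shares of cells with a UMI of a sex-linked gene or Gfp, cells were thinned to 5000 UMIs and shallower cells left out. Gene coordinates come from the GENCODE M21 annotation of GRCm38, the assembly also named mm10.

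Alternatives covered the scaling, the count filter, the block, Pth left out, the clustering resolution and genes, count splitting, doublets, the mitochondrial limit, all other cells as 1 class, DESeq2 1.42.0, each replicate left out, camera with an estimated correlation, and fry. The doublet score limit, and doublets kept in the replicate comparison, were added after the data had been examined. Glands that were not made by complementation were not analysed here.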

Results

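The data are 2 single-cell RNA-seq libraries of mouse parathyroid glands derived from embryonic stem cells in hosts without Gcm2. The libraries are replicates of 1 group and come from 8 mice. After filtering, 1240 cells with 39816872 UMIs were kept in replicate 1 and 3313 cells with 87142723 UMIs in replicate 2. The medians were 27223.5 and 27288 UMIs per cell. With a single group, cell classes were compared within the glands, and the replicates were set side by side.

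Gcm2, the gene the hosts lacked, was examined first. Gcm2 (ENSMUSG00000021362, chromosome 13, 41101427 to 41111035, GRCm38) encodes a transcription factor required for parathyroid gland formation. In the parathyroid-like class it reached 157 CPM (95% interval 153 to 162) in replicate 1 and 160.4 CPM (157 to 163) in replicate 2. A Gcm2 UMI was found in 95.6% and 96.6% of these cells. Over the 5 other classes compared, Gcm2 was at 2.43 and 3.28 CPM, and 4.23% and 4.10% of cells had a Gcm2 UMI. Parathyroid-like cells had medians of 37247 and 30508 UMIs, and fibroblast-like cells 21697 and 19727. The labels do not say which part of the host gene is deleted, so that a 3' tag outside it would check nothing. The tdTomato reporter reached 10559 ± 691 CPM against 151 ± 73.7 in the mean of the other classes.

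The composition of the glands was described next. Parathyroid-like cells made up 54.4% (95% interval 51.6 to 57.2) of replicate 1 and 66.6% (65.0 to 68.2) of replicate 2, or 60.5% ± 8.61 (SD, n = 2). Fibroblast-like cells made up 16.0% ± 3.45 and endothelial-like cells 8.68% ± 0.275. At a clustering resolution of 2 no cluster was named endothelial-like, and the unnamed share was 8.43%. Macrophage-like cells made up 4.47% ± 0.519. Dendritic-cell-like cells made up 4.92% of replicate 1 and 1.69% of replicate 2, and 0.512% on average with predicted doublets kept. T-cell-like cells made up 2.98% and 1.57% of the replicates, neutrophil-like cells 1.69% and 0.483%, and NK-like cells 1.94% and 0.181%. Pericyte-like cells made up 0.750% ± 0.0793, or 0.377% with each library clustered on its own, and 1.05% and 2.60% of cells stayed unnamed. The endothelial-like cluster was led by Gpihbp1 and Plvap, genes of capillary endothelium, and also by Ccl21a, a lymphatic gene. A Ccl21a UMI was found in only 2.43% ± 0.419 of these cells. The T-cell-like cluster was led by Cd163l1, Il23r, Trdc and Il17a, genes of gamma-delta T cells. The larger dendritic-cell-like cluster was led by Cd209a and also by Igkc, a B cell gene, and Top2a, a gene of dividing cells. Its marker score was 1.76 for dendritic cells and 1.73 for B cells. Over all dendritic-cell-like cells, an Igkc UMI was found in only 3.43% ± 0.207 and a Top2a UMI in 13.0% ± 4.41. These genes therefore do not describe most of the cells. The smaller one, of 17 cells, was led by Ccr7. Its Pth was at 1504 CPM in 11 cells of replicate 1 and 32769 CPM in 6 cells of replicate 2, where 1 cell held most of the Pth UMIs and the 9 Casr UMIs came from 1 cell. The counting intervals of the parathyroid-like share did not overlap between the replicates, and no test was made with 1 library each. Digestion and sorting can set these shares.

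**Figure D1:**
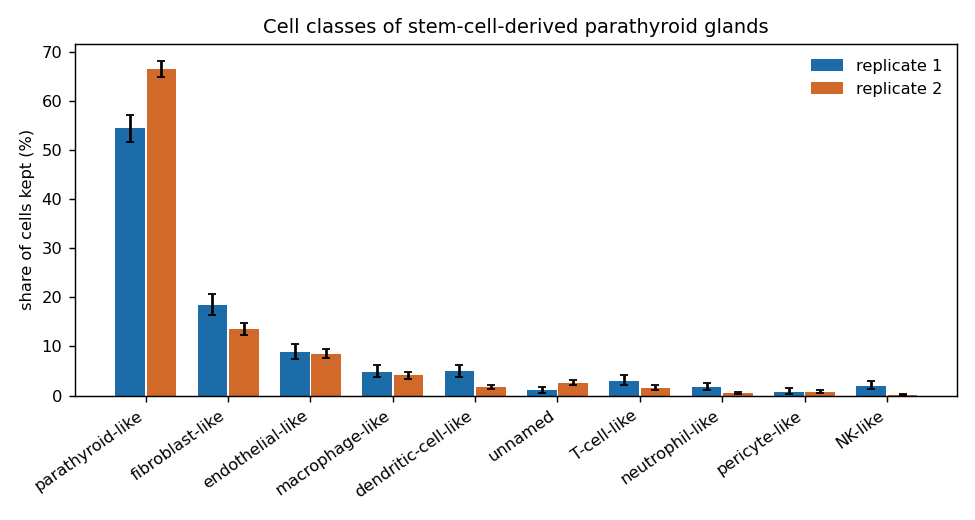
Share of kept cells (%) in each class, with 1 bar per replicate and exact binomial 95% intervals. Parathyroid-like cells made up 54.4% of replicate 1 and 66.6% of replicate 2.

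The main comparison asked what sets the parathyroid-like class apart from the mean of the 5 other classes. Parathyroid-like cells carried the reporter of the stem cells, while the other classes can hold host and stem cell progeny. Cell class and genetic origin therefore cannot be fully separated in the calls below. Pth (ENSMUSG00000059077, chromosome 7, 113385580 to 113388570), which encodes parathyroid hormone, took 14.2% and 15.9% of all UMIs of the class and from 0.118% to 0.572% elsewhere. The upper value rested on 1 dendritic-cell-like cell of replicate 2: without the cell of most Pth UMIs in each class and library the range was 0.117% to 0.220%. Chga, a granin of secretory granules, had 80893 ± 5556 CPM against 1123 ± 294. The transcription factor Gata3 had 376 ± 18.1 CPM against 28.7 ± 12.0. These markers helped to name the class and are not results. Casr, the calcium-sensing receptor (ENSMUSG00000051980, chromosome 16, 36493696 to 36562141), had 335 ± 24.2 CPM against 9.19 ± 3.40 (log2 fold change 5.95, SE 0.19, edgeR adjusted p = 9.74e-12). Gcm2 had 159 ± 2.08 CPM against 3.59 ± 1.21 (5.66, SE 0.23, edgeR adjusted p = 6.62e-11). Both were higher in 2 of 2 libraries. Relative to Pth, Casr and Gcm2 in fibroblast-like cells were at 0.826 (0.562 to 1.17) and 1.48 (0.976 to 2.15) times their parathyroid-like ratio. Free RNA or cell mixtures can thus hold counts of these genes in other classes, and the fold changes can understate the difference. Among 11326 eligible genes edgeR called 4742 higher and 2143 lower, of which 2934 and 1205 changed by 1 or more on the log2 scale. The median log2 fold change of eligible genes was 0.30, and 0.15 with DESeq2 size factors. Of the calls 68.9% were higher, against 55.2% with the DESeq2 test and 53.7% with all other cells summed to 1 class.

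The 12 largest higher genes were nearly absent from the other classes, and each had no UMI in 1 to 3 of the 5, where the contrast is poorly defined and the ranking uncertain. Rsph4a, a radial spoke protein, had 48.6 ± 7.41 CPM against 0.906 ± 0.211, Mak, a kinase of cilia, 25.3 ± 1.11 against 0.237 ± 0.220, Cfap69 44.5 ± 1.78 against 1.02 ± 0.132 and Efcab1 26.4 ± 1.14 against 0.306 ± 0.318. Erbb4, a receptor tyrosine kinase (chromosome 1, 68032186 to 69108059), was the most abundant of the 12 at 352 ± 14.4 CPM against 4.61 ± 4.84. The DM-domain genes Dmrtc1a (chromosome X, 102903216 to 102908687) and Dmrt2 had 38.7 ± 1.59 CPM against 0.357 ± 0.219 and 30.3 ± 2.28 against 0.462 ± 0.340. Kcna1, a potassium channel, had 22.7 ± 1.22 CPM against 0.208 ± 0.294, and Cldn3, a tight junction claudin that is also in the epithelial list, 51.6 ± 1.63 against 0.469 ± 0.334. Arhgef38 had 34.5 ± 7.93 CPM against 0.631 ± 0.834, Syne4 28.5 ± 3.84 against 0.308 ± 0.436 and the transcript BB218582 22.5 ± 0.825 against 0.221 ± 0.313. Mean CPM was 43.5 to 110.1 times that of the other classes. The fitted log2 fold changes of 7.83 to 9.18 depend on the prior count, since the other classes held only 6 to 104 UMIs of each gene. DESeq2 did not call Arhgef38, and Dmrtc1a has close copies, so that its count is uncertain.

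The 12 largest lower genes had 0 to 57 UMIs each in the parathyroid-like class. Msn, Gvin1, Ifit3, Lfng and Mfng were highest in endothelial-like cells and the others in macrophage-like, dendritic-cell-like or T-cell-like cells. Msn, which links the membrane to actin (chromosome X, 96096042 to 96168552), had 0.584 ± 0.0568 CPM against 429.9 ± 7.39, and Emp3 0.493 ± 0.0928 against 221 ± 44.8. No UMI of Gvin1 or Insyn2b was found in the parathyroid-like class. Against the limit of 3 counts over the class they were at least 752-fold and at least 883-fold lower than the mean of the other classes. P2rx7, an ATP-gated channel, and Was, a regulator of actin in blood cells, had 1 UMI each. The ratios were 3243 (582 to 128106) and 4213 (756 to 166410), with 95% counting intervals. Zbp1 and Mfng had 2 UMIs each, with ratios of 1087 (301 to 8978) and 1134 (314 to 9363). Ifit3, an interferon-induced gene that is also in the MHC list, had 52.8 ± 19.7 CPM in the other classes and 6 UMIs in the parathyroid-like class. Sp110 had 49.0 ± 4.96 CPM and 10 UMIs, Phf11b 45.1 ± 2.00 and 5, and Lfng, a modifier of Notch, 35.002 ± 6.36 and 5. All 12 were lower in 2 of 2 libraries, which the rule for named genes requires, with edgeR adjusted p from 9.68e-13 to 0.000138. Gvin1, Phf11b and Ifit3 have close copies, so that their counts are uncertain. The call of Insyn2b was lost at a clustering resolution of 2, with count splitting and with a doublet score limit, and that of Was at a resolution of 2.

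Transcription factors of the parathyroid and pharynx were higher as a list. In all 11 of 14 tested members were called higher and 2 lower by edgeR, with the same counts adjusted over the list alone. Besides Gcm2, Pax9, of pharyngeal pouch development, had 199 ± 10.8 CPM against 3.49 ± 1.47 and Eya1 181 ± 8.29 against 3.11 ± 2.85. Tcf21 had 0.0851 CPM against 14.6 and was not called. The list median was 4.44 (camera adjusted p = 0.00186 with the preset correlation, adjusted p = 0.204 with an estimated correlation). The camera call was lost with all other cells summed to 1 class, and 3 members called higher had a lower mean CPM than the other classes.

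Genes of calcium sensing, vitamin D and FGF23 signalling moved both ways: 9 of 21 tested members were called higher and 6 lower by edgeR, with the same counts adjusted over the list alone (camera adjusted p = 0.597). Kl, the co-receptor of FGF23, had 832 ± 37.5 CPM against 14.4 ± 4.76, and Vdr, the vitamin D receptor, 262 ± 67.0 against 18.7 ± 6.22, beside Casr. Arrb1, an arrestin, was lower at 0.776 ± 0.0646 CPM against 31.5 ± 1.64. Trpm7 had 101 CPM against 94.97 and was not called. A lower mean CPM than the other classes was found for 1 of the members called higher. Of genes of inherited parathyroid disease and parathyroid tumours, 11 of 21 tested members were called higher and 3 lower by edgeR, with the same counts adjusted over the list alone (camera adjusted p = 0.439). Besides Casr and Gcm2, Tbx1, a gene of the DiGeorge syndrome region, had 51.3 ± 0.633 CPM against 2.88 ± 0.405, while Fam111a was lower at 1.26 ± 0.307 CPM against 39.0 ± 6.42. Zfx had 49.3 CPM against 55.4 and was not called. Of the members called higher, 4 had a lower mean CPM than the other classes. With all other cells as 1 class the calcium sensing list was called lower.

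Secretory granule, prohormone processing and exocytosis genes were divided: 11 of 28 tested members were called higher and 6 lower by edgeR, with the same counts adjusted over the list alone (camera adjusted p = 0.701). Sytl4, a granule protein that binds Rab27, had 168 ± 29.4 CPM against 3.03 ± 1.69, Scg5, a chaperone of a prohormone convertase, 33.8 ± 0.241 against 2.89 ± 0.353, Unc13b, of vesicle priming, 47.2 ± 3.32 against 6.35 ± 1.66, and Cpe, a carboxypeptidase of prohormone processing, 57.0 ± 14.7 against 38.4 ± 5.54. Atp6ap2 had 103 CPM against 154 and was not called. The convertase genes Pcsk1, Pcsk2 and Pcsk5 had only 0.0143, 0.116 and 0.329 CPM in the parathyroid-like class. Other convertase genes of the list are not given here. A lower mean CPM than the other classes was found for 2 of the members called higher. The mean log2 fold change of the list was 0.87, and with all other cells as 1 class it turned to -1.24. Of endoplasmic reticulum folding and unfolded protein response genes, 11 of 37 tested members were called higher and 9 lower by edgeR, and 11 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.426). Ssr4, of the translocon, had 759.6 ± 102 CPM against 231 ± 36.3, Spcs1, of the signal peptidase, 301 ± 37.2 against 103 ± 12.0, and Selenos 214 ± 2.46 against 97.0 ± 12.1. Edem1, of misfolded glycoprotein disposal, was lower at 7.86 ± 1.53 CPM against 51.4 ± 1.47. Hsp90b1 had 391 CPM against 401 and was not called. A lower mean CPM than the other classes was found for 1 of the members called higher.

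Nuclear genes of oxidative phosphorylation were higher throughout the list: 53 of 53 tested members were called higher and 0 lower by edgeR, with the same counts adjusted over the list alone. Atp5e of the ATP synthase had 1739 ± 22.8 CPM against 537 ± 34.6, Ndufb9 of complex I 420.3 ± 28.3 against 146 ± 21.3, Cox8a of cytochrome oxidase 1327 ± 90.5 against 492 ± 58.6 and Sdhc of succinate dehydrogenase 121 ± 12.1 against 41.5 ± 8.73. The list median was 1.07 (camera adjusted p = 1.90e-12 with the preset correlation, adjusted p = 0.204 with an estimated correlation). With DESeq2 size factors 52 members were called higher and the median was 0.93. Of glycolysis and hypoxia response genes, 7 of 28 tested members were called higher and 8 lower by edgeR, with the same counts adjusted over the list alone (camera adjusted p = 0.245). Pfkp, a phosphofructokinase, was lower at 9.01 ± 0.0551 CPM against 168 ± 31.6, as were the glucose transporter gene Slc2a3 at 0.707 ± 0.0687 against 25.4 ± 2.51 and Ndrg1 at 0.182 ± 0.115 against 77.1 ± 8.05. Gapdh had 385 CPM against 397 and was not called. With all other cells as 1 class the glycolysis list was called lower.

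Epithelial adhesion and keratin genes were higher as a list: 23 of 28 tested members were called higher and 0 lower by edgeR, with the same counts adjusted over the list alone. The tight junction gene Cldn7 had 199.9 ± 26.5 CPM against 2.02 ± 0.710, the adhesion gene Epcam 1038 ± 113 against 24.5 ± 13.8, the keratin gene Krt18 267 ± 10.6 against 4.96 ± 3.91 and the protease inhibitor gene Spint2 309 ± 7.89 against 28.9 ± 3.22. Cd24a had 11.7 CPM against 129.97 and was not called. Of the members called higher, 2 had a lower mean CPM than the other classes. The list median was 5.53 (camera adjusted p = 2.11e-08 with the preset correlation, adjusted p = 0.204 with an estimated correlation). MHC and antigen presentation genes were lower: 0 of 30 tested members were called higher and 28 lower by edgeR, with the same counts adjusted over the list alone. Psmb8 of the immunoproteasome had 6.45 ± 1.61 CPM against 304 ± 15.9, B2m 80.7 ± 1.22 against 1788 ± 55.1, H2-D1 126 ± 1.13 against 1609 ± 85.2 and H2-Q7 0.396 ± 0.277 against 166 ± 28.2. H2-DMb1 had 2.18 CPM against 219 and was not called, with an SE of 66.3 on the log2 scale. The list median was -3.17 (camera adjusted p = 6.45e-18 with the preset correlation, adjusted p = 0.161 with an estimated correlation). The other classes include immune and endothelial cells, which carry many of these genes, and counts of MHC class I copies are uncertain.

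Immediate early and dissociation stress genes were lower as a list: 7 of 33 tested members were called higher and 20 lower by edgeR, with the same counts adjusted over the list alone. Ier5 had 7.27 ± 2.12 CPM against 255 ± 79.5, Nfkbia, an inhibitor of NF-kappaB, 143 ± 0.0194 against 1292 ± 144, Gadd45b 43.5 ± 4.18 against 454 ± 112 and Myc 0.0779 ± 0.0292 against 34.3 ± 5.13. Fos had 1819 CPM against 2080.4 and was not called. Of the members called higher, 2 had a lower mean CPM than the other classes. The list median was -1.03 (camera adjusted p = 2.03e-06 with the preset correlation, adjusted p = 0.204 with an estimated correlation). Of cell cycle genes, 1 of 26 tested members were called higher and 8 lower by edgeR, and 0 higher and 8 lower adjusted over the list alone. The replication genes Mcm3 and Mcm6 had 2.20 ± 0.598 CPM against 23.6 ± 3.90 and 3.07 ± 0.0814 against 20.5 ± 5.06, the centromere gene Cenpa 1.05 ± 0.0915 against 18.7 ± 0.3797 and Hmgb2 44.0 ± 3.18 against 231 ± 55.6. Kif23, the 1 member called higher, had a lower mean CPM than the other classes. Tuba1b had 125 CPM against 191 and was not called. The list median was -0.56 (camera adjusted p = 0.000558 with the preset correlation, adjusted p = 0.459 with an estimated correlation). The 8 genes called lower lay below at least 4 of the 5 other classes in each library, and the 4 named ones below all 5. Mki67 and Top2a, genes of mitosis, were not called. Mki67 was at 3.56 ± 0.574 CPM in parathyroid-like, 2.19 ± 0.241 in fibroblast-like, 3.24 ± 2.70 in endothelial-like, 1.15 ± 1.63 in T-cell-like and 13.7 ± 4.45 in macrophage-like cells. In dendritic-cell-like cells Mki67 was at 61.1 CPM in replicate 1 and 188 in replicate 2, and Top2a at 9.55 and 197 CPM.

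Angiogenic and vascular growth factors were divided: 6 of 24 tested members were called higher and 4 lower by edgeR, with the same counts adjusted over the list alone (camera adjusted p = 0.571). Vegfa and Vegfb, which act on endothelial cells, were higher at 88.3 ± 9.66 CPM against 61.5 ± 4.14 and 59.1 ± 1.80 against 18.1 ± 1.90. Tgfb1 and Pdgfb were lower at 21.6 ± 4.60 CPM against 146 ± 17.9 and 0.0994 ± 0.00116 against 83.5 ± 1.93. Efnb2 had 8.76 CPM against 40.7 and was not called. Of the members called higher, 3 had a lower mean CPM than the other classes, and with all other cells as 1 class the list was called lower, at a mean log2 fold change of -4.28. Of ion channel and membrane excitability genes, 8 of 29 tested members were called higher and 10 lower by edgeR, with the same counts adjusted over the list alone (camera adjusted p = 0.433). The calcium channel genes Cacna1d and Cacnb2 were higher at 147 ± 38.8 CPM against 33.9 ± 8.64 and 189 ± 7.503 against 11.4 ± 2.90, and the calcium pump gene Atp2b1 was lower at 73.9 ± 5.64 CPM against 491 ± 12.7. Kcnk1, a potassium channel, was called higher on the log scale, with 51.0 ± 5.61 CPM against 49.5 ± 23.6. Clcn3 had 62.0 CPM against 126 and was not called. With all other cells as 1 class the ion channel list was called lower.

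**Figure D2:**
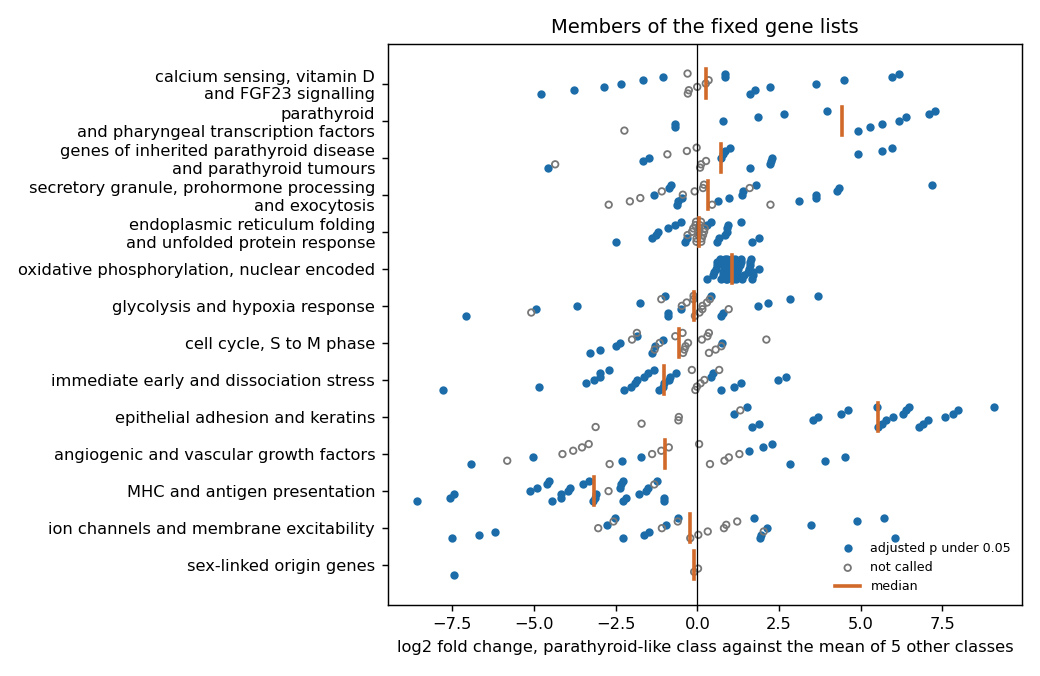
Log2 fold change (horizontal axis) of each tested member of the 14 gene lists, parathyroid-like class against the mean of 5 other classes; filled points passed an adjusted p of 0.05, open points did not, and bars mark list medians. The 53 oxidative phosphorylation genes lay above 0, and 28 of 30 MHC genes were called lower.

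Sex-linked genes were measured because the pools held males and females and the glands hold host and stem cell progeny. Xist, which silences an X chromosome in female cells (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), was lower in the parathyroid-like class, at 0.773 ± 0.162 CPM against 150.4 ± 11.6 (edgeR log2 fold change -7.46, adjusted p = 6.44e-08, lower in 2 of 2 libraries). At 5000 UMIs per cell a Xist UMI was found in 0.913% (95% interval 0.336 to 1.98) and 0.463% (0.222 to 0.850) of parathyroid-like cells. In fibroblast-like cells the share was 24.9% (19.4 to 31.1) and 24.9% (20.9 to 29.2). Without thinning the shares were 3.85% and 1.95% in parathyroid-like and 26.6% and 26.2% in fibroblast-like cells. Thinning left out 18 and 48 parathyroid-like cells and 4 and 8 fibroblast-like cells. A UMI of any of the 4 Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d was found in 0.152% and 2.13% of thinned parathyroid-like cells and in 1.33% and 3.62% of thinned fibroblast-like cells. Unthinned, the shares were 0.889% and 4.53%, and 2.62% and 6.22%. Of the sex-linked list, 0 of 3 tested members were called higher and 1 lower by edgeR, with the same counts adjusted over the list alone (camera adjusted p = 0.231). Tsix had 14.7 CPM against 18.7 and was not called. With all other cells as 1 class this list was called lower.

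**Figure D3:**
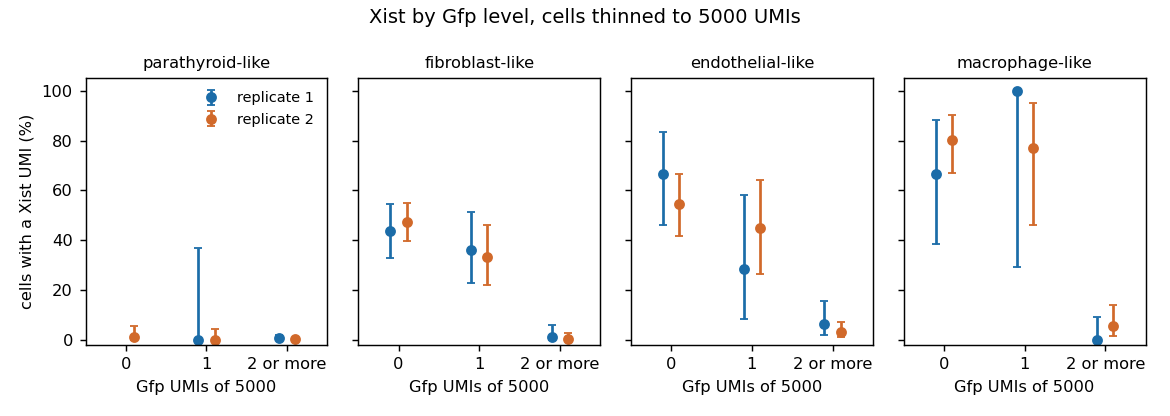
Percent of cells with a Xist UMI (vertical axis) by the number of Gfp UMIs (horizontal axis) in 4 classes, each cell thinned to 5000 UMIs; points are replicates and bars exact binomial 95% intervals. In fibroblast-like cells the share was 43.7% and 47.3% with no Gfp UMI and 1.10% and 0.521% with 2 or more.

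The parathyroid-like cells fell into 7 clusters, P1 to P7, which were compared over 342 tested list genes. edgeR called 67 of these in at least 1 cluster. The clusters were made from other genes of the same cells, with which list genes can vary. The p-values therefore do not test whether the clusters are separate kinds of cells. Nr4a1, an immediate early gene, was higher in P1 at 144 ± 22.5 CPM against 92.5 in the other clusters, and Scg5 was lower at 18.0 ± 6.57 CPM against 36.1. In P2, Tgfb1 (39.1 ± 13.2 CPM against 19.4), Scg5 (46.0 ± 4.83 CPM against 31.4) and Sytl4 (212 ± 29.3 CPM against 164) were higher. In P6 the genes of smallest p were the Y-linked Uty and Ddx3y, at log2 fold changes of 2.96 and 2.71 in replicate 2 and -0.26 and -0.12 in replicate 1. At least 2 Y-linked UMIs were found in 14.7% of P6 cells of replicate 2 and 0 of 60 of replicate 1. The calls of Cd74 in P1, Top2a in P2, Uty and Ddx3y in P4 (lower) and Kif11 in P5 also rested on 1 library. In P6, Maf (339 ± 3.69 CPM against 405), Jun (1297 ± 106 CPM against 1628) and Ssr4 (638 ± 74.7 CPM against 784) were lower. The genes given with CPM moved the same way in 2 of 2 libraries, with edgeR adjusted p from 2.56e-06 to 0.000635. In P7 edgeR called 0 genes, with 21 at an unadjusted p under 0.05, and no other tool was run. Without the replicate block 7 genes were called, and 155 at a clustering resolution of 2.

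The replicates were compared within the parathyroid-like class without a test, since each is 1 library. Pde10a, a phosphodiesterase, had 66.0 CPM (63.2 to 69.0) in replicate 1 and 239 CPM (236 to 243) in replicate 2. Sgk1, a kinase induced by serum and steroids (30.4 and 83.0 CPM), Gm43305 (33.4 and 78.0), Sytl3 (24.8 and 55.4) and Crem, a cAMP-responsive factor (88.6 and 193), also had more CPM in replicate 2. Polr2l (63.7 and 23.6), Lncpint (301 and 113), Neat1 (127 and 51.3), Klf4 (50.2 and 20.4) and A330033J07Rik (51.5 and 21.5) had more in replicate 1. Across 13311 genes with at least 1 CPM in a replicate, Pearson's r of log2 CPM was 0.982 and Spearman's rho 0.990, and genes are not independent replicates. Of 3013 genes with at least 50 CPM, 16 (0.531%) differed by 1 or more on the log2 scale. Library, mice and ages cannot be separated here.

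Residual stem cells were looked for through 8 pluripotency markers. A UMI of any marker was found in 3.87% (95% interval 2.87 to 5.10) of cells in replicate 1 and 2.29% (1.81 to 2.86) in replicate 2. No cell had UMIs of 2 or more markers. Pou5f1, which encodes Oct4, was found in 1.94% and 1.60% of cells. Nanog was found in 0 of 1240 cells (95% interval of the share with a UMI up to 0.297%) and in 3 of 3313. In replicate 1, 19 Tdgf1 UMIs came from 2 cells. A cell with these transcripts can show no UMI, and neither the detection rate in stem cells nor the background was measured, so that the share of stem cells is not limited by these values.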

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

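All tests in this part were chosen after the results had been seen.

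Cells of cluster N9 were left out of the comparisons, because they were set apart from the parathyroid-like clusters, and carried a parathyroid signal. All 52 cells came from replicate 2, with Pth at 126754 CPM, Gcm2 at 115 CPM and tdTomato at 8531 CPM. Dcn, a fibroblast gene, was at 2491 CPM, and 25 of the cells (48.1%) had a doublet score of at least 0.25.

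Cells of cluster N10 stayed unnamed because too few markers were detected, and were left out of the comparisons. In its 13 cells of replicate 1 and 34 of replicate 2, Il1rl1, the receptor of interleukin 33, was at 851 and 953 CPM. Areg was at 1709 and 1891 CPM and Il5 at 360.5 and 113 CPM, with an Il5 UMI in 6 and 8 cells.

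Xist was nearly absent from the parathyroid-like class, and fewer UMIs per cell are argued against, since the median UMIs of parathyroid-like cells were at least 1.55 times those of fibroblast-like cells in each library. A candidate explanation is that cells of the stem cell line carry no Xist and that Gfp marks them. In fibroblast-like, endothelial-like and macrophage-like cells, the Xist share among cells with 2 or more Gfp UMIs was at most 0.0968 times that among cells with none, in each library. Within the parathyroid-like class the absence of Xist did not follow Gfp: in replicate 2 the Xist share was 1.03% (0.0261 to 5.61) among 97 cells with no Gfp UMI, 0% (up to 4.35) among 83 with 1, and 0.455% (0.208 to 0.862) among those with 2 or more. The stem cells carry Pth-tdTomato, and the median parathyroid-like cell held 367 and 330 tdTomato UMIs, against 1 and 1 in fibroblast-like cells. A tdTomato UMI was found in 100% and 99.9% of thinned parathyroid-like cells. Cells of the stem cell line thus nearly lacked Xist in this class, with or without a Gfp UMI. The split by Gfp within this class therefore cannot test that part of the explanation. The labels give neither the sex of the stem cell line nor what Gfp marks, so that the rest stays open.

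Parathyroid transcripts were found in every other class compared. The ratios of Chga and tdTomato to Pth lay within 2 times of those in the parathyroid-like class in 20 of 20 values. Free RNA or cell mixtures can thus be their main source. The limit of 2 times is wide, and some ratios departed from 1 beyond their counting intervals. Chga was at 0.769 (0.727 to 0.813) and 0.757 (0.725 to 0.791) in macrophage-like cells. In endothelial-like cells of replicate 2 it was at 1.08 (1.05 to 1.11). Casr in dendritic-cell-like cells was first part of the same test and was set apart once it departed: its ratio was 4.60 (2.68 to 7.36) and 3.19 (2.25 to 4.40) times that of parathyroid-like cells, on 17 and 37 UMIs, which argues against free RNA as its whole source. Without the cell of most Pth UMIs, which in replicate 2 lowered the class from 5807 to 1319 Pth UMIs, the Casr ratio was 4.78 (2.79 to 7.65) and 10.6 (7.06 to 15.4), and those of Chga and tdTomato stayed within 2 times in all classes. Gcm2 in endothelial-like cells of replicate 2 also departed, at 2.54 (1.55 to 3.93), and 2.49 (1.24 to 4.46) without its cell of most Pth UMIs. In replicate 1 it was at 0.431 (0.0109 to 2.40) on 1 UMI, so that this departure rested on 1 library. Without the cell of most Pth UMIs, Gcm2 in dendritic-cell-like cells was at 0.628 (0.0159 to 3.50) and 3.76 (1.22 to 8.77), on 1 and 5 UMIs. Casr in macrophage-like cells was then at 2.02 (1.01 to 3.62) and 1.69 (0.985 to 2.71). No biological explanation was tested.

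Y-linked UMIs were found in a small part of the parathyroid-like cells of replicate 2: 72 of 2207 cells (3.26%) had at least 2, against 0 of 675 in replicate 1, with a 95% interval of up to 0.545%. Of these cells 40 were in cluster P6. Mixtures with male host cells or free RNA are argued against, since Eif2s3y and Kdm5d gave 1.53% (0.562 to 3.29) of the Y-linked UMIs and 22.1% (17.1 to 27.9) in all other cells of replicate 2. Reads of X-linked copies are argued against, since Y-linked CPM in replicate 1 was 0.0350 times that in replicate 2. The origin of these cells stays open, and no biological explanation was tested.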

How the results depend on the processing

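Of the alternatives, the doublet score limit and doublets kept in the replicate comparison were chosen after seeing the data. The counts of genes called higher and lower stayed within 1.5 times of the reported ones except where stated, and the cause was not tested unless the construction shows it. Without the replicate block 4383 genes were higher and 1910 lower, and 7 list genes were called between parathyroid-like clusters in place of 67; the block changed no list call. At a clustering resolution of 2 there were 155 such genes, of which 55 were shared. DESeq2 called 3925 higher and 3191 lower. With all other cells as 1 class, in which large classes weigh most by construction, 4614 genes were lower, 239 genes were called in the opposite direction, and 9 lists were lower. The mean log2 changes were then -1.24 for the secretory list, which turned, 1.23 for transcription factors, no longer called, and -0.66 (calcium sensing), -1.03 (glycolysis), -4.28 (angiogenic), -2.06 (ion channels) and -3.11 (sex-linked), all newly called. With an estimated correlation camera called 0 lists higher and 0 lower, so that the calls ended for transcription factors (mean 3.46), oxidative phosphorylation (1.08), cell cycle (-0.78), immediate early (-1.09), epithelial (4.24) and MHC genes (-3.44). With fry, which does not compare a list with other genes, 8 lists were higher; calcium sensing (0.52), endoplasmic reticulum (0.051) and ion channel lists (-0.24) turned against camera's direction, and disease genes (0.73), secretory (0.87) and sex-linked lists (-2.51) were newly called. With each replicate left out, without a test, list means were 2.89 to 3.52 (transcription factors), 0.55 to 0.70 (disease), 0.59 to 0.71 (secretory), 0.038 to 0.055 (endoplasmic reticulum), -0.40 to -0.31 (glycolysis), -1.07 to -1.05 (immediate early), 3.66 to 3.98 (epithelial), -3.32 to -3.29 (MHC) and -0.39 to 0.028 (ion channels, which turned without replicate 2). Of the genes called lower, 2138 to 2143 kept their sign. At a resolution of 2 the endothelial-like share was 0% and the unnamed share 8.43%. Each library clustered on its own left 5.78% unnamed and 0.377% pericyte-like. With doublets kept 0.512% were dendritic-cell-like, and with a stricter mitochondrial limit 0.668% pericyte-like. Without thinning, which raises the UMIs per cell by construction, a Xist UMI was found in 2.90% of parathyroid-like and 26.4% of fibroblast-like cells, and a Y-linked UMI in 2.71% of parathyroid-like, 4.42% of fibroblast-like and 6.64% of macrophage-like cells. With doublets kept 24.8% of fibroblast-like cells had a Xist UMI. The doublet score limit gave 4704 higher and 2135 lower genes. Depth limits genes near 0 UMIs and classes of few cells.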

Other observations

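The cilium lists were made after the names of the largest genes had been seen, and before the values of their members were.

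Because Cfap69, Rsph4a, Mak and Efcab1 were among the 12 largest higher genes, it was asked whether other cilium genes may be higher in the parathyroid-like class as a group. Both lists tested (2 of 2) were called higher by camera with the preset correlation. Of 40 listed genes of the motile axoneme 20 were tested, and edgeR called 18 of these higher and 1 lower (camera adjusted p = 2.28e-05 with the preset correlation, adjusted p = 0.101 with an estimated correlation). Members such as Hydin (6.61 CPM against 0.292) passed the count filter only through the parathyroid-like class. The number called higher among those tested is thus partly set by the filter. Of 45 listed genes of intraflagellar transport and the primary cilium 42 were tested, and edgeR called 35 of these higher and 1 lower (camera adjusted p = 8.30e-09 with the preset correlation, adjusted p = 0.0717 with an estimated correlation). Rsph9, of the radial spoke, had 149 ± 10.8 CPM against 6.15 ± 0.461, Dnah9, an axonemal dynein, 40.4 ± 3.32 against 0.686 ± 0.427, and Arl3, a GTPase of the cilium, 177 ± 11.2 against 40.6 ± 5.81. Cfap43 was lower at 2.36 ± 0.521 CPM against 12.5 ± 1.03, as was Arl13b at 34.6 ± 1.58 against 52.2 ± 7.55. Whether the cells bear cilia was not measured.

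Gfp was found in every class compared. It was at 4483 ± 814 CPM (SD, n = 2) in the parathyroid-like class, 6935 ± 1847 CPM in dendritic-cell-like cells and 647 ± 148 CPM in fibroblast-like cells. In fibroblast-like cells the Gfp UMIs were 2680 and 6669, against 207 and 289.7 expected from free RNA of parathyroid-like cells by the ratio to Pth. Free RNA of other classes was not measured.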
